A study of Mus musculus with 8 samples.

How the data were processed

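Total RNA was extracted from 4 liver tumours of mice with 1 Ctnnb1 allele whose exon 3 can be removed and from 4 livers of wild-type control mice. Per the labels' protocols, 750 ng of each RNA went into cDNA synthesis and in vitro transcription with biotin, and the copies were hybridized to Illumina mouse bead arrays. The deposited table of unnormalized values holds linear intensity per probe and array, which the submitters' processing notes credit to BeadStudio with no version. Background subtraction is not given in the sources used here, and no value fell below 30.6, so none was visible. The authors' deposited value table holds log2 signals that every array shares after sorting, as quantile normalization gives, in the rank order of the intensities (lowest Spearman correlation 1). Those log2 values differed from quantile-normalized log2 intensities by up to 0.29, so the reference distribution behind them is not known. Their median was 6.02 on every array.

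The design fixed before the data were examined called for a background correction from detection p-values or control probes. The intensity table carries neither, so the fallback written in the same design was used. Background was corrected in limma 3.58.1 (R 4.3.3) with the normexp method and an offset of 50, followed by quantile normalization between the 8 arrays and log2. Probes above the 40th percentile of an array on at least 4 arrays were tested, which kept 27576 of 45281. Linear models with empirical Bayes moderation (lmFit and eBayes, two-sided) compared the 4 tumours with the 4 normal livers. Benjamini-Hochberg adjustment ran over all tested probes, with a threshold of 0.05. Replicate numbers were not used as a block. On simulated arrays of 27559 probes built from this comparison, the procedure recovered 69 of 100 probes changed 2-fold and 95 of 100 with a log2 change of 2, with 13 false calls among 177. Simulated changes of log2 1 and 2 were estimated at medians of 0.96 and 1.90. The simulation changed 100 probes of each size, whereas 6361 probes passed the threshold in the real comparison. Recovery with that many changed probes was therefore not tested. The rates were not split by signal, so none can be read for dim probes. Figures were drawn with Python 3.11.15.

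Probes were named from the annotation of the array platform, which gives 1 symbol for 34885 probes, several for 18 and none for 10378. Updating through Entrez identifiers changed 0 symbols. Of the tested probes, 5183 have no name, and of these 473 were higher and 396 lower in the tumours past the threshold. A gene with several tested probes is represented by the probe with the highest mean over all 8 arrays. Of the genes past the threshold, 1829 have several tested probes, and for 15 another probe passed in the opposite direction. The files carry no detection calls, so a gene was taken as at background in a group when all 4 arrays lay at or under the 60th percentile of all probes (log2 6.57), a rule chosen after the data were seen. For such a gene the brighter group is set against that percentile and the result is given as at least N-fold. A probe stands for its target sequence only, and members of near-identical families cannot be told apart.

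The genes named were chosen by a rule fixed before the data were examined. It takes a panel of 28 genes around Ctnnb1, zonation and liver cancer, then the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, leaving out clone and predicted-gene names. It adds up to 4 members with the largest absolute change from each gene list. Of the panel, 23 genes were tested. The Lect2 probe stayed below the filter (highest log2 6.34), and Gls2, Sds, H19 and Mki67 have no probe under these names in the annotation used. The panel genes and leading genes come to 41. Hba-a1 and the genes of the plot of variable genes are named outside the rule and were chosen after their values were seen, as were the genes of the lists added later.

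The gene lists, 39 with the markers of other cell types, were written from textbook knowledge of mouse liver before the data were examined. Lists with at least 5 measured members, 37 in all, were tested with camera at its preset inter-gene correlation of 0.01 on the representative probes, with Benjamini-Hochberg adjustment over the lists. They were repeated with an estimated correlation and with fry. Members that rose or fell are those past the threshold over all probes, and each count is repeated adjusted over the list alone. Several genes stand in more than 1 list, so the lists are not independent. A further 10 lists were written after the fit had been seen and are used among the other observations, in weighing the granulocyte genes, in the check for arrays that stand apart and in the count of list genes that lost a call without 1 array.

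The alternatives were no background correction with an offset of 16, scaling to a common median, cyclic loess, the authors' normalized values, no filter, the average of a gene's probes, an intensity trend with robust variances, array weights, the replicate number as a block, no moderation of variances and each array left out in turn. A filter at the 60th percentile was added after the data were seen. The files name no genome build, so no coordinates are given, and the intensity table gives neither bead numbers nor chips, so those were not analysed here.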

Results

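Total RNA from 8 mouse liver and liver tumour samples was profiled on Illumina bead arrays, which read each transcript through biotin-labelled copies bound to gene-specific probes. The 4 tumour arrays came from liver tumours of mice whose Ctnnb1 gene carries 1 allele with exon 3 flanked by recombination sites. Loss of this exon removes the residues through which beta-catenin is marked for degradation, so the shortened protein is stable and active. The deposited title and design text call this model a knockout. The 4 normal liver arrays came from wild-type mice of the C57BL/6N background. Each array read 45281 probes, and 27576 of them, standing for 13640 named genes, were bright enough to be tested. Array medians of the deposited signals lay between 72.3 and 79.4 intensity units in normal liver and between 63.96 and 69.2 in tumours. The highest signals lay between 41383 and 47100 in normal liver and between 31728 and 37319 in tumours, so the groups did not overlap in either measure before normalization. Correlations of log2 signals across tested probes lay between 0.972 and 0.992 within the groups and did not exceed 0.963 between them, where the probes are not independent replicates. The number of arrays limits the precision. The labels do not say which animal each sample came from, so p-values measure only the spread between these samples. Values below are normalized log2 signals, changes are tumour minus normal liver with the standard error, n = 4 arrays per group, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

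The comparison of tumours with normal liver asks which transcripts differ in tumours with active beta-catenin. In the tumours, 22 of 33 measured genes of the hepatocytes around the central vein and 12 of 23 Wnt target genes rose, and 18 of 27 genes of the hepatocytes around the portal vein fell. As whole lists, these shifts passed with a preset correlation and not with an estimated one (adjusted p = 0.0782, 0.185 and 0.188 with an estimated correlation). Glul, the glutamine synthetase of the innermost pericentral cells, rose by 2.61 ± 0.08 (6.11-fold). Cyp2f2, a periportal cytochrome P450, fell by 5.11 ± 0.55 (34.6-fold) and Hal, the first enzyme of histidine breakdown, fell by 4.81 ± 0.29. Single genes also rose for 24 of 38 in the cell cycle list, 15 of 25 NRF2 targets of antioxidant defence and 16 of 29 oncofetal and tumour markers, and fell for 13 of 23 genes with higher expression in male than in female liver. These 4 lists did not pass with an estimated correlation either (adjusted p = 0.339, 0.339, 0.131 and 0.339 with an estimated correlation). Tumour 3 stood apart from the other tumours for several gene groups, among them markers of neutrophils and of Kupffer cells.

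In all, 3694 genes (27.1% of those tested) passed an adjusted p of 0.05 in limma, 1839 higher and 1855 lower in the tumours. Of these, 822 changed at least 2-fold, 524 of them higher and 298 lower; with arrays scaled to a common median, 464 were higher and 379 lower. All 4 tumours lay above or all 4 below the normal livers for 3976 genes (29.2%), against 2.86% by chance. That chance share takes tumour 4 as an independent array and would be higher otherwise. The median change of all genes was -0.02. Tumour 4 lay within the range of the other 3 tumours at 623 of the 626 genes that varied among those 3 (99.5%), whereas the other 7 arrays lay within the range of the rest of their group at 30.6% to 81.6% of such genes. Without tumour 4, 2465 genes passed (1250 higher and 1215 lower) and 723 of them changed at least 2-fold, and 2455 of the 2465 had also passed with all 8 arrays.

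The targeted gene, Ctnnb1, did not pass: its brightest probe read 12.88 ± 0.23 (SD) in normal liver and 12.98 ± 0.26 in tumours, a change of 0.10 ± 0.15 (limma adjusted p = 0.702) whose sign varied with the setting (-0.23 to 0.20). None of the 4 Ctnnb1 probes passed. The files do not say where in the transcript the probes lie, so these values do not check the deletion of exon 3.

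Of 23 measured Wnt feedback and target genes, 12 rose, 2 fell and 9 did not pass; adjusted over the list alone, 12 rose and 3 fell. The list shifted upward as a whole with the preset correlation of camera (adjusted p = 2.22e-05), and not past the threshold with the correlation estimated from these arrays (adjusted p = 0.185 with an estimated correlation). Nkd1, an inhibitor induced by Wnt signalling, rose by 3.14 ± 0.23 (adjusted p = 3.46e-05), and the transcription factor Sp5 by 2.58 ± 0.13. Axin2, which acts in beta-catenin breakdown and is a standard readout of the pathway, rose by 2.52 ± 0.16. Ccnd1, which encodes cyclin D1, rose by 2.10 ± 0.14 and Lgr5, a receptor for R-spondins, by 1.79 ± 0.08. Myc read 6.19 in normal liver and 6.20 in tumours, at background in both, so no change can be read from it. Without tumour 4, 12 members rose and 1 fell.

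Of 33 measured pericentral hepatocyte genes, 22 rose and none fell, also adjusted over the list alone (22 and 0). Besides Glul (adjusted p = 3.50e-07), the glutamate transporter Slc1a2 rose by 2.80 ± 0.12, the ammonium transporter Rhbg by 2.98 ± 0.24 and the retinol dehydrogenase gene Rdh9 by 3.09 ± 0.23. The glutathione transferase gene Gstm3 rose by 4.36 ± 0.25, Tbx3 by 1.70 ± 0.15, Oat by 0.65 ± 0.10 and Cyp1a2 by 1.08 ± 0.27. Cyp2e1 read 14.76 in normal liver and 14.69 in tumours (adjusted p = 0.625). Both means lay above log2 13, the level set here for possible saturation, so a change may not show. Oat (14.39 and 15.05) and Cyp1a2 (13.01 and 14.09) also had both means above that level and still rose, so it does not hide every change. When arrays were scaled to a common median in place of quantile normalization, Cyp2e1 was lower (-0.57) and Oat (0.24) and Cyp1a2 (0.72) no longer passed. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, varied widely in both groups (11.58 ± 1.66 against 12.33 ± 1.06, SD) and did not pass (adjusted p = 0.563). Its change was 0.75, and 0.10 without normal liver 2. The list was higher with the preset correlation (adjusted p = 4.27e-12; adjusted p = 0.0782 with an estimated correlation), and 19 members rose without tumour 4.

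Of 27 measured periportal hepatocyte genes, 18 fell and none rose, and 21 fell adjusted over the list alone. The median change was -1.62, and the shift passed with the preset correlation (adjusted p = 5.04e-10; adjusted p = 0.188 with an estimated correlation). Cyp2f2 fell from 14.17 to 9.06 (adjusted p = 0.000246) and Hal from 12.35 to 7.54 (adjusted p = 1.40e-05). Pck1, the gluconeogenic PEP carboxykinase, fell by 3.26 ± 0.47 and the phospholyase gene Etnppl by 3.12 ± 0.40. Without tumour 4, 16 members fell.

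Genes of the urea cycle and ammonia detoxification split along the same lines. Of 15 measured, 8 fell and 4 rose (9 and 4 adjusted over the list alone). Arg1, the last enzyme of the cycle, fell by 3.11 ± 0.20 and Cps1, its first enzyme, fell by 2.94 ± 0.49, with the lowest Cps1 signal in tumour 3 (9.06). The members that rose included Glul, Rhbg and Oat, which are already counted among the pericentral genes, so their rises are not a separate result. The list as a whole was lower (adjusted p = 0.0318; adjusted p = 0.512 with an estimated correlation).

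**Figure D1:**
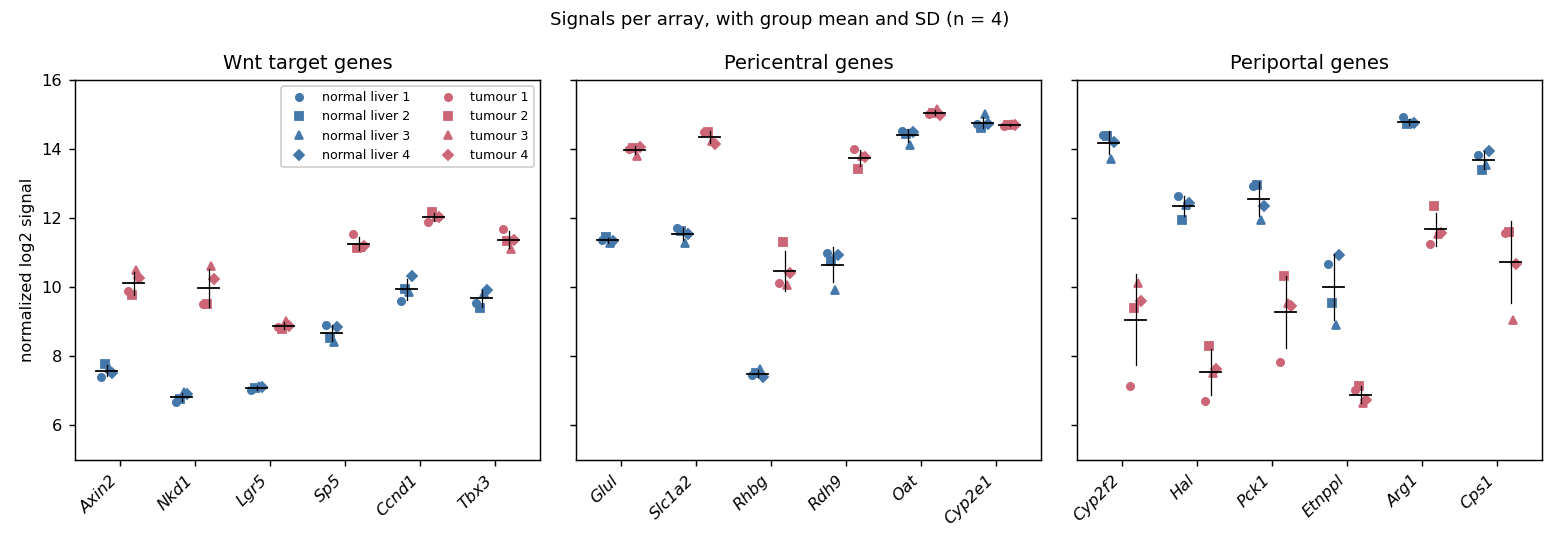
Normalized log2 signal (vertical axis) of 6 Wnt target, 6 pericentral and 6 periportal genes, 1 marker per array, with group means as horizontal lines and SDs as vertical lines (n = 4). The Glul means are 11.35 in normal liver and 13.96 in tumours, the Cyp2f2 means 14.17 and 9.06, and the Cyp2e1 means 14.76 and 14.69.

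The 10 largest rises among genes whose groups did not overlap were led by Ly6d, a surface antigen best known from lymphoid and epithelial cells, at 7.16 ± 0.19 (adjusted p = 1.55e-07). The others were Pnliprp1, Plat (5.03), Nupr1 (4.89), Gstm3, Gstp2 (4.22), Cbr3 (4.17), Fgf21 (4.14), Gpx2 and Igf2bp3. Without tumour 3 the change of Gpx2 was 4.70, against 4.10 with all arrays. Pnliprp1, Gpx2 and Igf2bp3 lay at background on all 4 normal livers and were at least 28.9-fold, 14.5-fold and 11.7-fold higher in the tumours. These bounds set the tumour mean against the 60th percentile of all probes (log2 6.57). Plat encodes tissue plasminogen activator, Fgf21 a hormone of the fasting response and Gpx2 a glutathione peroxidase. Gstp2 has a near-identical neighbour, so its signal cannot be assigned to 1 gene with certainty.

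The 10 largest falls were those of Cyp2f2, Hsd3b5 (-5.10), Hal, Cyp8b1 (-4.06), Bdh2 (-3.92), Aspg (-3.78), Serpina1e (-3.60), Cd163 (-3.54), Enho (-3.50) and Upp2 (-3.50). Hsd3b5 is a steroid dehydrogenase of male liver, Cyp8b1 makes the precursor of cholic acid and Cd163 is a scavenger receptor of macrophages. Serpina1e belongs to a family of near-identical genes and is uncertain for that reason. Its tumour signals ran from 8.93 in tumour 1 to 13.14 in tumour 3, its change was -2.85 without tumour 1 and -4.26 without tumour 3, and its call was lost with no moderation of variances (adjusted p = 0.0511, with a range of 0.00218 to 0.0511 over its alternatives). The change of Cyp2f2 was -4.50 without tumour 1.

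Oncofetal and liver tumour markers rose for 16 of 29 measured genes and fell for 1; adjusted over the list alone, 17 rose and 1 fell. Afp, the main fetal serum protein, rose by 2.83 ± 0.29 (adjusted p = 0.000201) and Gpc3, a proteoglycan used as a marker of liver cancer, by 0.61 ± 0.18 (adjusted p = 0.0355). Cbr3 rose in every tumour (11.57 ± 0.77, SD, against 7.39 ± 0.06). Igf2, a fetal growth factor, read 14.48, 13.69 and 13.48 in tumours 1, 2 and 4 and 7.16 in tumour 3, against a normal liver mean of 7.04 (adjusted p = 0.0230). The calls of Gpc3, Igf2, Cyp1a2 and Alb were lost without tumour 4 (adjusted p = 0.0606, 0.0722, 0.0596 and 0.0518), and those of Gpc3 and Igf2 also without other single arrays. All of these genes also lost the call with no moderation of variances, and Gpc3 with the replicate block (limma adjusted p = 0.0750). The change of Igf2 was 6.88 without tumour 3 and 4.43 without tumour 1, against 5.17 with all arrays. Over its alternatives the adjusted p of Igf2 ran from 1.34e-06 to 0.0924. The list was higher with the preset correlation (adjusted p = 5.62e-07; adjusted p = 0.131 with an estimated correlation).

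Cell cycle and mitosis genes rose for 24 of 38 measured members and fell for 2 (27 and 2 adjusted over the list alone). The spindle midzone gene Prc1 rose by 2.66 ± 0.32, Cdc20, an activator of the anaphase-promoting complex, by 2.02 ± 0.32 and the spindle gene Nusap1 by 1.99 ± 0.26. Pbk lay at background in normal liver and was at least 3.50-fold higher. Top2a, a topoisomerase of dividing cells, was at least 1.22-fold higher (adjusted p = 0.0120). The mean change of the list was largest in tumour 3 (1.01) and smallest in tumour 2 (0.46). As a whole the list was higher (adjusted p = 7.75e-09; adjusted p = 0.339 with an estimated correlation).

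NRF2 targets rose for 15 of 25 genes and none fell (17 and 1 adjusted over the list alone). Gstm3 and Cbr3 led the list, followed by the export pump Abcc4 (3.32 ± 0.18) and Gsta1 (3.09 ± 0.50), whose sequence is close to that of Gsta2. The median change was 1.21 (adjusted p = 9.96e-08; adjusted p = 0.339 with an estimated correlation), and 14 members rose without tumour 4. Drug metabolism genes moved both ways: 17 of 53 rose and 10 fell (17 and 12 adjusted over the list alone), among them Cyp2c55 (3.94 ± 0.50) and Cyp2f2, and the list as a whole did not pass (adjusted p = 0.326). Without tumour 4, 11 drug metabolism genes rose and 7 fell.

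Male-biased liver genes fell for 13 of 23 members and rose for 1 (16 and 2 adjusted over the list alone), with a median change of -1.93. Hsd3b5 fell by 5.10 ± 0.63, the major urinary protein gene Mup21 fell by 3.28 ± 0.70 and the glucuronosyltransferase gene Ugt2b1 fell by 3.03 ± 0.36. Without tumour 1 the change of Mup21 was -2.50. Mup21 belongs to a family of near-identical genes. Female-biased genes rose for 6 of 21 members and none fell, also adjusted over the list alone (6 and 0), with Cyp4a14 (3.05 ± 0.85) and Acot3 (2.11 ± 0.62) among them. Without normal liver 3 these 2 changes were 2.02 and 1.45, and that of Cyp4a14 was 3.65 without normal liver 4. Cyp2a4 had a change of 2.65 ± 1.06 that did not pass. The male-biased list was lower (adjusted p = 3.48e-06) and the female-biased list higher (adjusted p = 0.00376), both with adjusted p = 0.339 with an estimated correlation. Without tumour 4, 10 male-biased genes fell and 2 female-biased genes rose. Of 4 measured sex chromosome genes, the Y-linked Kdm5d fell by 0.54 ± 0.12 and the others did not pass (0 rose and 1 fell, also adjusted over the list alone). Xist lay at background in the tumours, and the Y-linked Eif2s3y read 10.71 or more in every tumour.

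Gluconeogenesis and glycogen genes fell for 6 of 16 and rose for 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0265; adjusted p = 0.339 with an estimated correlation). Beside Pck1, the glucose-6-phosphate transporter gene Slc37a4 fell by 1.10 ± 0.21 and the glycogen synthase gene Gys2 by 0.95 ± 0.28. G6pc, at -1.38 ± 0.73, did not pass, and tumour 1 alone read low (8.67). Oxidative phosphorylation genes fell for 16 of 39 and rose for 1 (19 and 3 adjusted over the list alone; adjusted p = 0.000768; adjusted p = 0.363 with an estimated correlation), with Sdhb of complex II at -0.86 ± 0.14 and Ndufa9 of complex I at -0.59 ± 0.09. Bile acid synthesis and transport genes fell for 9 of 25 and rose for 5 (10 and 5 adjusted over the list alone), with Cyp8b1 and Cyp7b1 (-2.43 ± 0.21) lower and Abcc4 higher. That list did not pass (adjusted p = 0.193), except under scaling to a common median (0.0359, with a range of 0.0359 to 0.271 over its alternatives). The gluconeogenesis list was not called without normal liver 4 (adjusted p = 0.0806, with a range of 0.00313 to 0.0806). Without tumour 4, 1 gluconeogenesis gene rose and 4 fell, and 10 oxidative phosphorylation genes fell.

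Fatty acid oxidation and ketogenesis genes rose for 5 of 26 and fell for 1 (6 and 2 adjusted over the list alone; list adjusted p = 0.450), among them Fgf21 and Pdk4 (1.73 ± 0.42), a kinase that restrains pyruvate use. Lipogenesis and lipid storage genes rose for 7 of 29 and fell for 8 (8 and 8 adjusted over the list alone; list adjusted p = 0.868). The lipid droplet gene Cidec rose by 3.08 ± 0.68, and Thrsp, which promotes lipogenesis, fell by 2.20 ± 0.47. Cholesterol synthesis genes rose for 5 of 16 and fell for 4 (5 and 5 adjusted over the list alone; list adjusted p = 0.831), with Sqle at 1.05 ± 0.26 and Tm7sf2 at -0.85 ± 0.17. In these 3 lists the median lay just below 0 and the test leaned upward. Glycolysis genes rose for 4 of 17 and fell for 1 (5 and 1 adjusted over the list alone; list adjusted p = 0.213), with Aldoa (1.39 ± 0.42) and Pkm (1.08 ± 0.13) higher. Without tumour 4, fatty acid oxidation genes rose for 2 and fell for none, lipogenesis genes rose for 4 and fell for 7, cholesterol synthesis genes rose for 3 and fell for 2, and glycolysis genes rose for 2.

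Secreted products of hepatocytes were lower for part of the lists. Complement and coagulation genes fell for 12 of 34 and rose for 1 (13 and 1 adjusted over the list alone; adjusted p = 0.000389; adjusted p = 0.339 with an estimated correlation). The terminal complement genes C9 (-3.12 ± 0.50), C8b (-2.09 ± 0.17) and C8a (-1.80 ± 0.20) fell most. Acute phase genes fell for 4 of 25 and rose for 1, also adjusted over the list alone (4 and 1; adjusted p = 0.0304; adjusted p = 0.612 with an estimated correlation). Saa1 fell by 2.99 ± 0.61, Saa2, whose sequence is close to that of Saa1, by 2.69 ± 0.76, and Saa4 by 2.80 ± 0.31. The change of Saa1 was -2.40 without tumour 1. That of Saa2 was -3.34 without normal liver 1 and -2.05 without normal liver 3, where its call was lost (adjusted p = 0.0564). The mean of this list was higher in normal livers 2 and 3 (0.41 and 0.58 above the normal mean) than in normal livers 1 and 4 (-0.27 and -0.72), and its call was lost without normal liver 2 (adjusted p = 0.0890), normal liver 3 (0.143) or tumour 3 (0.0751), against 0.000506 to 0.143 over its alternatives. Without tumour 4, 2 acute phase genes fell. Hepatocyte identity genes fell for 8 of 27 and rose for 1 (10 and 1 adjusted over the list alone; adjusted p = 0.00633; adjusted p = 0.339 with an estimated correlation). Tdo2, which opens the tryptophan ring, fell by 2.03 ± 0.21, the bile acid receptor gene Nr1h4 by 0.70 ± 0.12 and Alb by 0.69 ± 0.17 (adjusted p = 0.0157), the last on a probe reading only 9.01 in normal liver. Without tumour 4, 8 complement and coagulation genes and 5 hepatocyte identity genes fell.

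**Figure D2:**
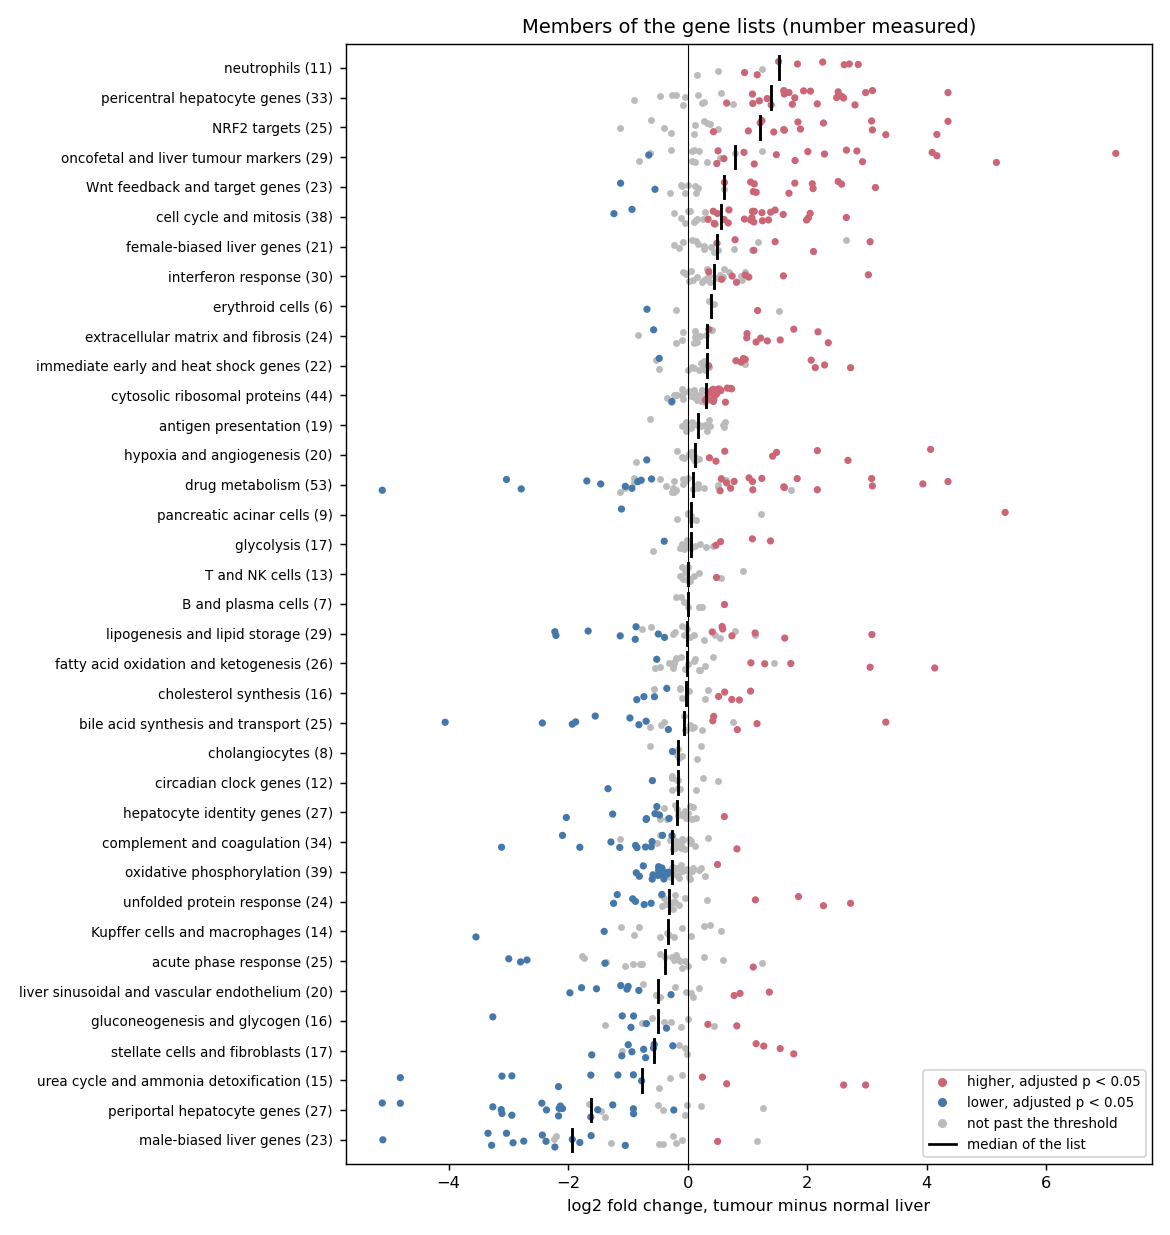
Log2 fold change (horizontal axis) of each measured member of the 37 tested gene lists, 1 point per gene, ordered by the median of the list (black line); red and blue points passed an adjusted p of 0.05. The median is 1.40 for pericentral genes, -1.62 for periportal genes and -1.93 for male-biased genes; the upward shift of the ribosomal proteins was lost, and its sign turned, when arrays were scaled to a common median.

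Stress and signalling lists followed. Immediate early and heat shock genes rose for 9 of 22 and fell for 1 (10 and 2 adjusted over the list alone; adjusted p = 0.000453; adjusted p = 0.339 with an estimated correlation), with the transcription factor genes Atf3 (2.73 ± 0.19) and Klf6 (2.29 ± 0.22) and the small heat shock protein gene Hspb1 (2.07 ± 0.31). Unfolded protein response genes went both ways, 4 of 24 rising and 7 falling (4 and 9 adjusted over the list alone; list adjusted p = 0.174). The members that rose included Atf3, Trib3 (2.27 ± 0.43) and Ddit3 (1.85 ± 0.29), which act in the stress response downstream of Atf4, and Chac1 fell by 1.24 ± 0.36. Hypoxia and angiogenesis genes rose for 8 of 20 and fell for 1 (8 and 2 adjusted over the list alone; adjusted p = 0.0258; adjusted p = 0.363 with an estimated correlation). The endothelial genes Esm1 and Angpt2 rose by 4.07 ± 0.41 and 2.68 ± 0.38, and Ndrg1 by 2.17 ± 0.35. Without tumour 4, 5 genes of this list rose. The unfolded protein response list passed only under scaling to a common median (adjusted p = 0.0119, with a range of 0.0119 to 0.298 over its alternatives).

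Cytosolic ribosomal protein genes rose for 23 of 44 and fell for 1 (27 and 3 adjusted over the list alone; adjusted p = 7.92e-07; adjusted p = 0.339 with an estimated correlation), by a median of 0.30, and with arrays scaled to a common median the direction turned and the list did not pass (adjusted p = 0.938, the highest of its alternatives, which start at 1.87e-08). Rps12 rose by 0.74 ± 0.08 and Rpl12 by 0.72 ± 0.13 under the main normalization. Circadian clock genes fell for 2 of 12, also adjusted over the list alone (0 rose and 2 fell; list adjusted p = 0.291), with Ciart at -1.33 ± 0.22 and Tef at -0.59 ± 0.16.

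Interferon response genes rose for 8 of 30 and none fell, also adjusted over the list alone (8 and 0; adjusted p = 0.000324; adjusted p = 0.555 with an estimated correlation). Usp18, which curbs interferon signalling, rose by 3.02 ± 0.14 and the antiviral gene Rsad2 by 1.02 ± 0.25. The mean change of the list was 1.0 in tumour 1, 0.87 in tumour 2, 0.50 in tumour 4 and -0.09 in tumour 3, the tumour in which neutrophil and Kupffer cell markers were also lowest. None of 19 antigen presentation genes passed, also adjusted over the list alone (0 and 0; list adjusted p = 0.193), although that list passed without normal liver 1 (adjusted p = 0.0216) or tumour 3 (0.0104), with a range of 0.0104 to 0.694 over its alternatives. Without tumour 4, 5 interferon response genes rose.

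Neutrophil markers rose for 8 of 11 genes and none fell (9 and 0 adjusted over the list alone; adjusted p = 0.000453; adjusted p = 0.438 with an estimated correlation). S100a8 and S100a9, the calprotectin subunits, rose by 2.70 ± 0.70 and 2.62 ± 0.71, and Mpo, the peroxidase of their granules, was at least 4.95-fold higher. Without tumour 3 the changes of S100a8 and S100a9 were 3.31 and 3.23, and the bound of Mpo was 8.45-fold. The mean change of this list was 2.24, 2.37 and 1.56 in tumours 1, 2 and 4 and 0.31 in tumour 3, and only 2 members rose without tumour 4. Kupffer cell and macrophage markers fell for 2 of 14, also adjusted over the list alone (0 and 2; list adjusted p = 0.186), of which Cd163 fell by 3.54 ± 0.29 and Marco fell by 1.40 ± 0.20. Their mean change was -1.60 in tumour 3, -0.70 in tumour 4, -0.18 in tumour 1 and 0.21 in tumour 2, and the list passed without tumour 2 (adjusted p = 0.0135, with a range of 0.0135 to 0.868 over its alternatives).

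Markers of liver sinusoidal and vascular endothelium fell for 8 of 20 and rose for 3 (10 and 3 adjusted over the list alone; adjusted p = 0.0173; adjusted p = 0.438 with an estimated correlation). Wnt2, a Wnt ligand made by central vein and sinusoidal endothelium, fell by 1.97 ± 0.14 and the sinusoidal lectin gene Clec4g by 1.53 ± 0.34, while Lyve1 rose by 1.37 ± 0.40. Without tumour 4, 7 of these genes fell and 1 rose. Stellate cell and fibroblast markers fell for 9 of 17 and rose for 4 (10 and 4 adjusted over the list alone; adjusted p = 0.0421; adjusted p = 0.339 with an estimated correlation), with Ecm1 lower (-1.61 ± 0.20) and Col3a1, Col1a2 and Acta2 higher by 1.78, 1.55 and 1.27. This list's call was lost under scaling to a common median (adjusted p = 0.0847), with the filter at the 60th percentile (0.0899), and without normal liver 2 (adjusted p = 0.102) or tumour 2 (0.104), with a range of 0.0123 to 0.104 over its alternatives. Extracellular matrix and fibrosis genes rose for 10 of 24 and fell for 1 (10 and 2 adjusted over the list alone; adjusted p = 0.000389; adjusted p = 0.339 with an estimated correlation). Col4a1, a basement membrane collagen, rose by 2.18 ± 0.20, and the collagenase gene Mmp13 was at least 4.34-fold higher.

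Few markers of the remaining cell types passed. T and NK cell markers rose for 1 of 13, also adjusted over the list alone (1 and 0; list adjusted p = 0.373), which was Prf1 (0.47 ± 0.11). The B and plasma cell markers rose for 1 of 7, also adjusted over the list alone (1 and 0; list adjusted p = 0.706), which was Cd79b (0.60 ± 0.15). Cholangiocyte markers fell for 1 of 8 and for none adjusted over the list alone (0 and 0; list adjusted p = 0.503). That gene, Pkhd1, lay at background in the tumours. Erythroid markers rose for 1 of 6, Tfrc (1.17 ± 0.34), and fell for 1, Alas2 (-0.68 ± 0.20), also adjusted over the list alone (1 and 1; list adjusted p = 0.538). The haemoglobin gene Hba-a1 read 14.13 ± 0.85 (SD) in normal liver and 14.49 ± 0.34 in tumours. None of 3 adipocyte markers passed, also adjusted over the list alone (0 and 0), and with the 4 sex chromosome genes they were too few for a list test. Pancreatic acinar markers rose for 1 of 9 and fell for 1, also adjusted over the list alone (1 and 1; list adjusted p = 0.445). Pnliprp1 rose, while Amy2a5 (-1.11 ± 0.16) fell and Clps was at background in both groups. Without tumour 4, no T and NK cell, B and plasma cell, cholangiocyte or erythroid marker passed.

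**Figure D3:**
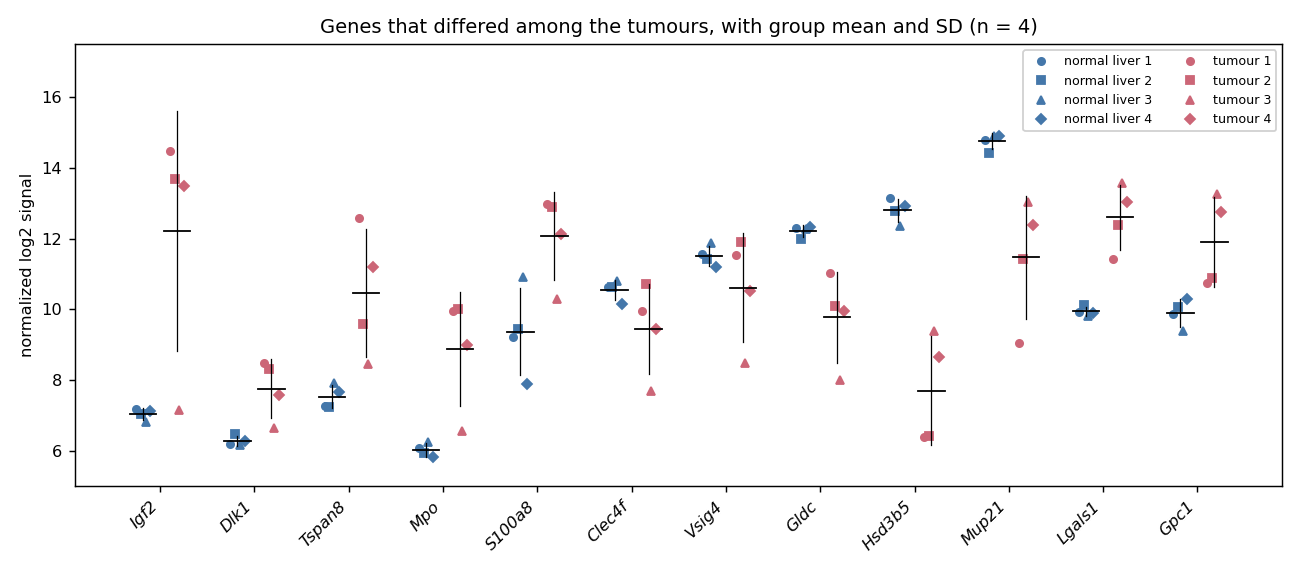
Normalized log2 signal (vertical axis) of 12 genes that varied among the tumours, chosen after their values were seen, with 1 marker per array, group means as horizontal lines and SDs as vertical lines (n = 4). Tumour 3 reads 7.16 for Igf2, near the normal livers, while tumours 1, 2 and 4 read 13.48 to 14.48, and tumour 4 lies between the other tumours for each gene drawn.

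Of the 37 lists tested, 22 passed with the preset correlation (12 higher and 10 lower), and none passed with an estimated correlation, where 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0782. The stellate cell list had an estimated correlation of 0.0086, under the preset 0.01, yet its unadjusted camera p rose from 0.0251 to 0.0643. The size of the correlation therefore does not explain every lost call. By fry, which does not compare a list with other genes, 22 lists moved 1 way on balance and 34 changed in either direction. Changes of genes near background are low estimates.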

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

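The tests on tumour 4 and on the sex-biased genes were chosen only after the results they bear on were seen, as was the count of erythroid precursor genes near background. The tests on the granulocyte genes and on other splits of the arrays were fixed before their results were seen.

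Tumour 4 lay between the other tumours, with 0 genes outside their range by over 0.5 log2, against 58 to 500 for the other 7 arrays. At that margin tumour 4 showed no differences of its own like those of the others. The count restates the pattern that prompted it, so it is not a separate test of that explanation. A weighted sum of the linear signals of tumours 1, 2 and 3 (weights 0.30, 0.16 and 0.54) followed it with a residual SD of 0.11, against 0.25 to 0.35 when other arrays were modelled in the same way. The share of tumour 3 read from 23 genes low in tumour 3 (0.562) and from 22 genes high in it (0.556) differed by 0.00561. Tumour 4 may therefore hold RNA or tissue of the kinds in the other tumours, which would leave 3 independent tumours. Pooled RNA and a tumour built of both kinds of cells were not separated by these tests, and no biological explanation was tested.

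The male-biased genes fell by a median of 1.93 while the female-biased genes rose by a median of 0.49. Female tumour mice set against male controls are argued against, since the lowest tumour signal of the Y-linked Eif2s3y lay 4.14 above the 60th percentile of all probes and no Xist probe exceeded 6.47 in a tumour. A lower share of hepatocytes as the whole cause is argued against as well: the 11 hepatocyte identity genes below log2 13 in normal liver changed by a median of -0.52 (quartiles -0.62 and -0.17). The 12 male-biased genes below the same level fell by a median of 1.17, a gap to the hepatocyte genes larger than their interquartile range, and the median of the female-biased genes lay above 0. A lower share may still account for part of the fall, a loss of the male pattern of liver expression within the tumour cells could give both shifts, and the ages and hormone levels of the mice were not analysed here.

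Granulocyte genes were high in tumours 1, 2 and 4 and near the normal livers in tumour 3, with Mpo at 9.94, 10.01, 8.98 and 6.57. Blood left in the tissue could bring them, but the test was open. The median change of 4 precursor genes exceeded that of 7 mature granulocyte genes by 0.27, 0.66 and 0.39 log2 in tumours 1, 2 and 4. That gap passed the bound of 0.5 only in tumour 2. In tumour 3 it was 0.33, so it did not follow the granulocyte signal. Prtn3, among the 4 precursor genes, ran from 6.59 to 11.52 in normal liver. Hba-a1 (14.73, 14.76 and 14.44) stayed below the highest normal liver (15.05), and Hbb-bs read 15.22 in each (highest normal liver 15.15). Such equal values mark the same rank after quantile normalization. Both haemoglobin genes lay above log2 13 on every array, the level applied to the hepatocyte genes, so a change may not show in full. Hba-a1 still ran from 13.15 to 15.05 among the normal livers. Among the tumours both genes were lowest in tumour 3 (14.03 and 14.97), as the granulocyte genes were, but inside the range of the normal livers. They therefore leave blood open. Haematopoietic precursors in the tissue could bring the granulocyte genes too. Slc4a1, on the earlier erythroid list as well, read 10.03, 9.81, 7.13 and 8.98 in tumours 1 to 4 (normal livers 6.64 to 9.004). Trim10 read 7.17, 7.12, 6.25 and 6.72 (5.92 to 6.81). Neither passed (limma adjusted p = 0.151 and 0.165). Of the 9 erythroid precursor genes, 0 rose past the threshold and 2 fell, Klf1 (-0.61) and Tspan33 (-1.73), both lower in every tumour than in any normal liver. The highest median change of the 8 erythroid precursor genes other than Slc4a1 among tumours 1, 2 and 4 was 0.057, under the bound of 0.1 set beforehand, but that bound was a poor one because 5 of the 8 genes never rose 0.5 log2 over the 60th percentile, so these sources cannot be told apart. Activated neutrophils entering tumours 1, 2 and 4 remain open as well, untested. Tumour 4 may hold RNA or tissue of the kinds in the other tumours, so it may not be a separate case here.

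The 8 arrays were also split into 4 and 4 in other ways. Only the real split, 1 of 35, gave 3694 genes, and the highest count of any other split was 0. For changes of at least 2-fold the real split, again 1 of 35, gave 822 and the highest other 0. Every other split mixes tumours with normal livers, so a real difference widens its spread. A count of 0 there is therefore no measure of false calls. The rank of the real split is all that these counts show, and it takes tumour 4 as an independent array. For the gene lists with the preset correlation, 2 of the 35 splits, the real split included, called 22 lists. The rival split set normal liver 1 with tumours 1, 3 and 4. Most arrays kept their true groups in it, so it still carried part of the real difference. Its tie therefore cannot weigh chance, which was not excluded for the number of list calls.

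Single arrays far from the other 3 of their group, by Dixon's criterion, were found in 21 of 388 groups of signals for 194 genes, and chance marks about 1 group in 20. Among the tumours, tumour 3 was low for Igf2 (7.16, others 13.48 to 14.48), Glul (13.80) and Cd79b (6.74). Tumour 1 was low for G6pc (8.67) and Myc (6.17), the latter at background. Tumour 2 was high for Enho (6.95), Upp2 (9.497), Ftcd (12.31) and Afmid (9.22) and low for Col3a1 (8.98). Among the normal livers, normal liver 3 was low for Acot1 (8.54, others 11.60 to 12.22), Ciart (8.72), Lyve1 (8.84) and Ccrl2 (6.95) and high for Ndrg1 (10.04) and Rpl35 (13.47). Normal liver 1 was high for Arg1 (14.92) and Sult2a2 (7.13), normal liver 2 was high for Acta2 (9.46) and low for Col1a2 (6.58), and normal liver 4 was low for Ankrd37 (6.77).

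Probes without a gene name were left out of the gene counts, and 473 of them were higher in the tumours past the threshold.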

How the results depend on the processing

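All alternatives here were fixed before the data were examined except the filter at the 60th percentile. The count of genes past the threshold ran from 2669 with no moderation of variances to 5021 with array weights, and the count changed at least 2-fold from 669 with averaged probes to 915 with array weights. Leaving out 1 array gave 2465 to 3390 genes, 723 to 899 changed at least 2-fold, and 20 to 23 lists. The lowest gene counts came without tumour 4. The share of higher genes was 49.8%, and 40.6% with arrays scaled to a common median, where 2905 of 3239 genes had also passed in the main setting. Cyp2e1, Oat, Cyp1a2 and the ribosomal protein genes, all bright, moved down under that scaling. With the filter at the 60th percentile 3623 genes and 21 lists passed.

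The number of lists past the threshold was 0 with an estimated correlation in camera, where 4 had an unadjusted p under 0.05, and 34 with the mixed test of fry; the latter asks another question. The other list settings gave 21 or 22. The shift of the ribosomal protein list reversed under scaling to a common median (adjusted p = 0.938); the cause was not tested. Of 409 comparisons of named genes with other settings, 9 lost and 1 gained a call, and no called gene changed sign. Of 328 that left out 1 array, 14 lost a call, all of Gpc3, Igf2, Cyp1a2 or Alb. Of 199 called genes that lead the lists or belong to the added lists, 43 lost the call without at least 1 array and none changed sign. Of those printed, Acot3, Cyp4a14, S100a8, S100a9, Saa2, Tfrc, Alas2, Aldoa, Chac1, Gys2, Lyve1, Tef, Pkhd1 and Ccrl2 lost it without several arrays, and Cd79b, Pdk4, Prf1, Sqle and Chil3 only without tumour 4. Of 256 list comparisons other than the estimated correlation, 2 lost a call, 2 gained 1 and 1 reversed, and of 296 that left out 1 array, 6 lost and 3 gained a call.

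With the replicate number as a block, 3125 genes passed, 805 changed at least 2-fold and 22 lists passed. Deviations of same-numbered arrays correlated by 0.06, -0.03, -0.15 and 0.08, and only normal liver 1 correlated best with the tumour of its own number. These values show no clear pairing by number, but so few arrays cannot exclude a weak shared effect. The detection p filter and the chip block were not run, since the intensity table carries neither, and the planned normexp correction with an offset of 50 is the main setting. Member counts of lists were recomputed only without tumour 4, a choice made after the data were seen. Signals near background limit the folds of dim genes.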

Other observations

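The gene lists and tests here were chosen only after the comparison of tumours with normal liver had been seen, and share genes with the lists above. Genes of amino acid breakdown fell in part or all of each list described. All 4 measured genes of histidine degradation fell, also adjusted over the list alone, with Amdhd1 at -3.04 ± 0.33 and Uroc1 at -2.36 ± 0.23 following Hal in the same pathway; the list was too short for a list test. Of 9 genes of tryptophan degradation, 8 fell and none rose, also adjusted over the list alone (limma camera adjusted p = 1.60e-05; adjusted p = 0.216 with an estimated correlation). Tdo2 opens this pathway, and Kynu (-1.34 ± 0.17) and Kmo (-0.85 ± 0.09) act further along it. Of 7 genes of tyrosine and phenylalanine degradation, 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.00303; adjusted p = 0.216 with an estimated correlation): Hpd fell by 1.26 ± 0.16 and Fah by 0.80 ± 0.08, while Hgd, which acts between them, rose by 0.70 ± 0.15. Serine, glycine and threonine genes fell for 6 of 14 and rose for 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0343; adjusted p = 0.216 with an estimated correlation), with Gldc of glycine cleavage at -2.44 ± 0.52 and Psat1 of serine synthesis at 1.89 ± 0.25. Without tumour 3 the change of Gldc was -1.86. Without tumour 4, the falls counted 4, 8, 6 and 5 in these 4 lists.

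Imprinted genes rose for 8 of 14 measured members and fell for 2 (8 and 3 adjusted over the list alone; adjusted p = 0.0331; adjusted p = 0.333 with an estimated correlation). Igf2 led, and Dlk1, at background in normal liver, was at least 2.27-fold higher, with signals of 8.48, 8.32, 6.64 and 7.58 in tumours 1 to 4. Impact rose by 1.21 ± 0.20 and Igf2r, the receptor that clears Igf2 protein, by 0.99 ± 0.16, while Ndn fell by 1.20 ± 0.13. Without tumour 4, 7 rose and 2 fell.

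Granulocyte precursor genes rose for 7 of 9 and none fell (8 and 0 adjusted over the list alone; adjusted p = 0.00303; adjusted p = 0.355 with an estimated correlation), and for 1 without tumour 4. The lectin gene Chil3 read 10.73, 10.88, 6.96 and 9.78 in tumours 1 to 4, and its change was 3.90 without tumour 3, against 3.02 with all arrays. Of 7 mature granulocyte genes, 1 fell, Ccrl2 (-0.34 ± 0.11), and none did adjusted over the list alone (list adjusted p = 0.887). Erythroid precursor genes fell for 2 of 9 and none rose, also adjusted over the list alone (list adjusted p = 0.887): Tspan33 (-1.73 ± 0.15) and Klf1 (-0.61 ± 0.14).

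Of 8 metallothionein and zinc transport genes, 1 rose and none fell, also adjusted over the list alone (list adjusted p = 0.887), and that was the zinc importer gene Slc39a4 (3.10 ± 0.23), with all 4 tumours between 12.39 and 13.32 against 9.34 to 10.05 in normal liver. The median of that list was -0.21 and its mean 0.05. Retinoid metabolism genes rose for 4 of 16 and fell for 4, also adjusted over the list alone (4 and 4; list adjusted p = 0.887), and without tumour 4, 3 rose and 2 fell. Rdh9 and the carotenoid-cleaving Bco1 (1.30 ± 0.17) were among those that rose, and Cyp26a1, which breaks down retinoic acid, fell by 1.05 ± 0.23. In this list too the median (-0.19) and the mean (0.03) differed in sign.

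On normal liver 1, a pair of Xist probes, both left out by the filter, read 6.99 and 7.03, while no other array exceeded 6.07 on either of them. The remaining Xist probes read 6.36 and 6.14 on this array, inside the range of the other arrays. Its Y-linked Eif2s3y (11.81) and Kdm5d (8.56) lay within the range of the other normal livers.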
